A study of Mus musculus with 2 samples.

How the data were processed

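RNA was sequenced from whole lung tissue of wild-type C57BL/6 mice aged 6 to 8 weeks, 3 days into intranasal dosing with an adenovirus, per the labels. Adenovirus is used here as a delivery vehicle that carries a gene into cells of the airway and lung. The virus was either an empty vector (Adv-EV) or a vector for interleukin 17B (Adv-IL-17B). The labels name total RNA as the molecule and standard Illumina library protocols, and the design text names a HiSeq instrument. The labels give 1 sample per group, and the samples were grouped by their titles. The design text speaks of triplicates. Whether each library holds RNA of a single mouse or of several is not given in the sources used here.

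The deposited table holds FPKM values, which are fragments scaled by transcript length and by the library total, in 1 column per group, rounded by the authors to 2 decimals per the file headers and the values. It has 17943 genes, each with a symbol and its RefSeq transcript accessions. Bowtie2 and HISAT are named, with no versions, in the submitters' processing notes, which also name the mouse genome build mm10. The step that turned alignments into FPKM values, its annotation version, any filter on reads or genes and the handling of strand and multiply mapped reads are not given in the sources used here. FPKM divides by transcript length and by the library total, so a few abundant genes can shift all others, and reads of near-identical genes may have been split between them. The 26 symbols deposited as dates were named again from their RefSeq accessions. No gene of the table was at 0 in both libraries. Genes encoded by the mitochondrial genome, immunoglobulin and T cell receptor segments and transcripts of the virus were not analysed here.

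The depth of each library was estimated from the steps in its low values. FPKM times transcript length is a whole multiple of a fixed amount where whole fragments were counted. Lengths came from GENCODE mouse release M21, on the same assembly as mm10, for 17462 genes (97.3%). The step search used genes with 1 transcript of at most 3000 bp, of which 1468 (Adv-EV) and 1464 (Adv-IL-17B) had low values. Only steps from 0.15 to 0.25 FPKM for a transcript of 1 kb were searched. A depth outside that range could not have been found. In both libraries 1 fragment was worth 0.182 FPKM for a transcript of 1 kb, which makes about 5510000 fragments per library. With that step, 77.2% and 76.2% of the low values lay within 0.2 of a whole number of fragments. A value of 0 in a transcript of 1 kb allows up to 0.544 FPKM, the level of 3 fragments. For genes with several transcripts the longest was taken, so their fragment numbers are approximate. In both libraries the estimated fragments summed over genes came to more than the estimated total of the library. The depth is therefore a rough estimate, and all fragment numbers, intervals and floors share its uncertainty. The fragment numbers were used for intervals and for depth only, and no count test was run. Each interval on a ratio of 2 values is an exact Clopper-Pearson 95% interval on the estimated fragments. Such intervals and floors cover counting error only, not differences between mice, dissections or library preparations.

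Ratios were taken as log2(FPKM + 0.1) in Adv-IL-17B minus the same in Adv-EV. The pseudocount of 0.1 makes these ratios understate the difference of genes with low values, so folds printed with an interval are plain ratios of the deposited FPKM values. Genes with a mean of at least 0.5 FPKM were kept. With 1 sample per group no difference could be set against a spread between replicates, so no test was run and no p-value is given. Genes were counted as higher or lower by a rule of size, a log2 ratio of at least 1 or at most -1, which is 2-fold. Choices of unit scale, filter, size rule, gene lists, named genes and alternatives were made before the data were examined, apart from the alternative and the lists said to have been added later.

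A total of 48 gene lists covered cytokine, chemokine and interferon pathways, tissue functions, markers of cell types that lung tissue or its dissection could hold, and genes that report on RNA quality, stress or time of day. The median log2 ratio of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart when its percentile lay within 2.5 of either end. This places a list within these libraries and is not a test of the treatment. Of the 43 lists with a percentile, about 2.15 would stand apart by chance if genes of a list were unrelated.

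The named genes were all measured members of the IL-17 family and receptor list, of the proinflammatory cytokine list and of the list of neutrophil-attracting CXC chemokines, and members of these lists under the filter are given too. To these were added the 12 genes with the highest and the 12 with the lowest ratio among genes of at least 5 FPKM in the higher library and above 0 in both. Predicted genes (symbols of Gm and a number, ending in Rik or starting with LOC) were left out of that ranking and of the named genes listed at 0. Up to 5 genes listed at 0 in each library and up to 4 members of every list with the largest absolute ratio completed the names, with Gapdh, Actb and sex-linked genes as checks. Members named beyond this rule are said to have been chosen after their values were seen.

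The calculation was tested on simulated data. Across 20 simulations of 17462 genes with counting error alone and no true difference, the size rule called a mean of 145 genes higher and 146 lower in Adv-IL-17B against Adv-EV. With at least 20 estimated fragments over both libraries these means were 31 and 30. Of 50 genes simulated at each size in the same comparison, the rule recovered 100% at a log2 ratio of 1.5, 92% at -1.5, 100% at 2.5 and 100% at -2.5. Of 200 lists drawn at random from the simulated genes, the changed ones among them, 14 stood apart. Random lists do not show how often lists of genes that vary together would stand apart.

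Alternatives were a pseudocount of 1 or 0.01, no filter or a filter at a mean of 5 FPKM, a size rule of 1.5-fold or 4-fold, values rescaled to the same total or to a median log2 ratio of 0, and the mean of a list in place of its median. A filter at 20 estimated fragments was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.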

Results

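Gene expression was measured by RNA sequencing in the lungs of C57BL/6 mice, a common inbred laboratory strain, after 3 days of intranasal adenovirus. The virus was either an empty vector (Adv-EV, n = 1 library) or carried the cytokine interleukin 17B (Adv-IL-17B, n = 1 library). IL-17B is a member of the IL-17 family of secreted cytokines and binds the receptor encoded by Il17rb. The comparison addressed which genes, proinflammatory cytokine genes among them, differ in expression in lung given IL-17B. The table held FPKM values of 17943 genes, which summed to 539847 in Adv-EV and 547075 in Adv-IL-17B. Each library had about 5510000 fragments as roughly estimated from the steps in its values, a total that the estimated fragments summed over genes exceeded. The 10 most abundant genes held 16.6% of the summed FPKM in Adv-EV and 13.5% in Adv-IL-17B. With 1 library per group no difference below has a replicate check. All intervals are 95% intervals, and they cover counting error only unless called bootstrap intervals. Bootstrap intervals come from resampling the genes of a list and cover only the spread between those genes.

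Il17b itself was listed at 0 in the Adv-EV library and at 93.2 FPKM in the Adv-IL-17B library, about 356 fragments. A value of 0 for its transcript of 693 bp allows up to 0.786 FPKM. The mouse gene lies on the plus strand of chromosome 18, from 61684887 to 61692538 of mm10 (RefSeq NM_019508). The values do not show whether those fragments came from the vector or from the mouse gene. Il17rb, the receptor subunit that binds IL-17B, stood at 0.61 FPKM in Adv-EV and 0.17 in Adv-IL-17B, or about 7 and 2 fragments (3.59-fold lower, interval 0.666 to 34.5). Il17ra, the shared receptor subunit, stood at 14.2 and 20.98 FPKM (1.48-fold higher, interval 1.33 to 1.64). Il17re, the receptor subunit for IL-17C, stood at 17.7 and 12.2 FPKM, and Il17rd at 6.54 and 4.36. Il17rc stood at 16.5 and 14.2 FPKM, and Traf3ip2, the adaptor Act1 of IL-17 receptors, at 6.8 and 5.6. Il17d was at 5.91 FPKM in Adv-EV and 2.95 in Adv-IL-17B (interval of the ratio 1.13-fold to 3.48-fold lower). Il17a stood at 0.16 and 0.47 FPKM, about 1 and 3 fragments (2.94-fold, interval 0.240 to 157). Il17c and Il17f were listed at 0 in Adv-EV and at 0.57 and 0.15 FPKM in Adv-IL-17B, about 2 fragments and 1. Of the 7 measured members of the IL-17 family and receptor list, 1 (Il17b) was past the size rule. The list's median log2 ratio of -0.28 lay at percentile 4.49 of its random lists, within their range, whereas the mean of 1.12, set by Il17b, had the opposite sign.

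Among 15056 measured genes, 594 were at least 2-fold higher and 404 at least 2-fold lower in the Adv-IL-17B library. The highest ratios among named genes of at least 5 FPKM in the higher library and above 0 in both were those of the following 12 genes. Asprv1, an aspartic protease, stood at 1.17 FPKM in Adv-EV and 17.3 in Adv-IL-17B (14.8-fold higher, interval 7.83 to 31.5). Acod1, which makes the antimicrobial metabolite itaconate in activated macrophages, stood at 4.71 and 51.3 FPKM (10.9-fold higher, interval 8.49 to 14.2). The medium-chain fatty acid receptor gene Gpr84 was 8.79-fold higher (1.12 and 9.84 FPKM, interval 4.56 to 17.7). Clec4e, the Mincle receptor for microbial glycolipids, was 6.43-fold higher (5.69 and 36.6 FPKM, interval 5.06 to 8.26). The chemokine genes Cxcl5, Cxcl2, Cxcl3, Ccl2 and Ccl3 and the stefin gene Stfa2l1 (2.80 and 17.8 FPKM) completed this group, together with the microRNA genes Mir5131 and Mir1306. By the estimate these microRNA genes rested on about 10 and 4 fragments in Adv-IL-17B and about 0 in Adv-EV (0.39 and 0.21 FPKM). A value above 0 at less than 1 fragment means that counting in whole fragments, or the length used, does not hold for them. Fragment numbers, intervals and floors of small RNA genes are therefore uncertain.

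The lowest ratios under the same rule were also those of 12 genes. Cidec, a lipid droplet protein gene, stood at 5.19 FPKM in Adv-EV and 0.53 in Adv-IL-17B (9.79-fold lower, interval 3.93 to 31.5). Zbtb16, which encodes the transcription factor PLZF, stood at 11.3 and 2.37 FPKM (4.76-fold lower, interval 3.64 to 6.27). The haemoglobin genes Hba-a1 and Hbb-bt were 3.67-fold and 3.37-fold lower, and Dbp, a clock-driven transcription factor gene, was 3.23-fold lower. Krt79 (5.36 and 1.61 FPKM), Fam107a (7.14 and 2.29 FPKM) and the Hoxa cluster antisense transcript Hotairm1 (10.6 and 3.25 FPKM) also belonged here. Without known strand handling, reads of Hotairm1 and of overlapping genes cannot be told apart. So did the small RNA genes Rpph1, Mir130c, Mir7036 and Mir6935, on about 11, 9, 9 and 7 fragments in Adv-EV and 2 each in Adv-IL-17B, and the intervals of the last 3 included equal levels. Of the genes listed at 0 in Adv-EV, predicted genes left out, Il17b had the highest value in Adv-IL-17B. It was followed by Mir671 (28.0 FPKM), Mir7087 (10.4), Mir6990 (9.61) and Snord32a (7.83). These small RNA genes rested on about 15, 4, 5 and 4 fragments. For them a 0 in Adv-EV allows up to 5.56, 7.78, 5.98 and 6.56 FPKM. Those listed at 0 in Adv-IL-17B, again without predicted genes, were led by Mir6989 (18.3 FPKM in Adv-EV), Mir546 (16.7), Mir3113 (13.2), Mir6385 (12.8) and Snord12 (11.8). They rested on about 7, 11, 6, 7 and 6 fragments in Adv-EV. For them a 0 in Adv-IL-17B allows up to 8.38, 4.5, 7.16, 5.19 and 6.05 FPKM. All these fragment numbers, intervals and floors of small RNA genes rest on counting in whole fragments, which did not hold for Mir5131 and Mir1306.

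The median log2 ratio of the measured genes was -0.01, the interquartile range ran from -0.24 to 0.23, and 93.4% stayed inside the 2-fold limits. Across genes, the log2 values of the libraries had a Pearson r of 0.939, where genes are not independent replicates. The counts depend on depth. Genes with at least 20 estimated fragments over both libraries numbered 13851, of which 379 were higher and 200 lower, against means of 31 and 30 from counting error alone in simulated unchanged libraries. Without that limit the simulated means were 145 and 146, against the 594 and 404 genes above. Small RNA genes, whose short transcripts hold few fragments, made up 66 of the higher and 55 of the lower genes out of 174 measured.

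**Figure D1:**
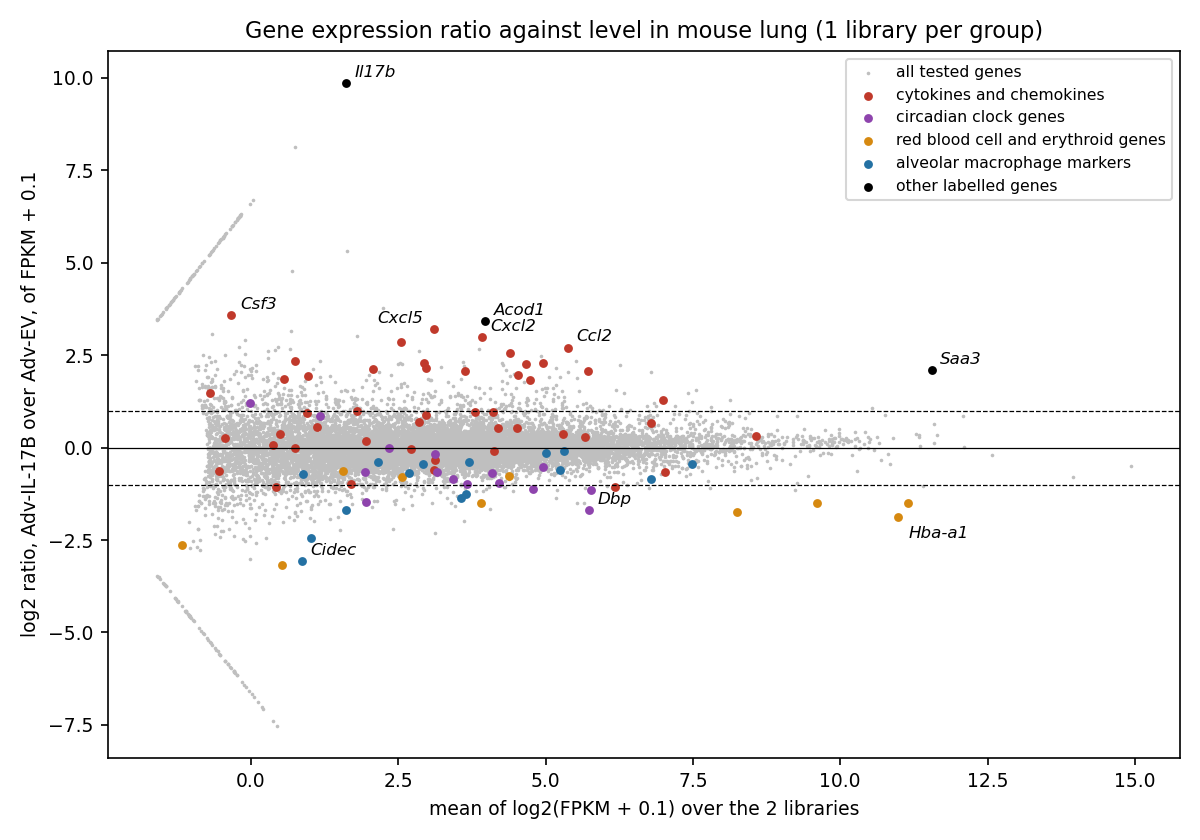
Log2 ratio of Adv-IL-17B over Adv-EV on FPKM + 0.1 (vertical axis) against the mean log2(FPKM + 0.1) of the 2 libraries (horizontal axis), with 1 point per measured gene and dashed lines at log2 ratios of 1 and -1. Cytokine and chemokine genes such as Cxcl5 and Ccl2 sit above the upper line, Hba-a1, Dbp and Cidec sit below the lower one, and the diagonal arms are genes listed at 0 in either library.

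Several proinflammatory cytokine genes were higher in the Adv-IL-17B library. Of 17 measured members, 6 were higher by the size rule (5 with a pseudocount of 1, without Il23a) and 0 lower, with a median log2 ratio of 0.54 at percentile 99.96. Tnf, a central inflammatory cytokine gene, stood at 3.39 FPKM in Adv-EV and 16.9 in Adv-IL-17B (4.98-fold higher, interval 3.32 to 7.47). The IL-1 genes Il1b (14.0 and 49.7 FPKM) and Il1a (1.91 and 8.63 FPKM) were 3.55-fold and 4.52-fold higher. Il6 stood at 0.67 and 2.71 FPKM on about 4 and 17 fragments (4.04-fold higher, interval 1.39 to 17.4). Csf3, which encodes the neutrophil growth factor G-CSF, rested on about 1 and 21 fragments at 0.13 and 2.65 FPKM (20.4-fold, interval 3.38 to 868). Il23a stood at 0.27 and 0.93 FPKM on about 2 and 7 fragments, with an interval of its ratio from 0.666 to 34.5. Osm (2.36 and 4.80 FPKM) and Lif (1.30 and 2.59 FPKM), genes of IL-6-type cytokines, and Tslp, an epithelial alarmin gene (4.45 and 2.22 FPKM), lay just inside the limit on FPKM + 0.1. On plain FPKM, Osm was 2.03-fold higher and Tslp 2.0045-fold lower (interval 1.02 to 4.11). Csf1 stood at 18.9 FPKM in Adv-EV and 27.5 in Adv-IL-17B, Il33 at 46.1 and 56.6, Csf2 at 3.54 and 4.06, Il12b at 1.14 and 1.5 and Il12a at 0.57 and 0.71. Il18 (6.60 and 6.37 FPKM) and Il27 (1.58 in both) were nearly equal. Ifng stood at 0.75 and 0.45 FPKM on about 5 and 3 fragments. Tnfsf11 was at 0.08 FPKM in Adv-EV and listed at 0 in Adv-IL-17B. Only 3 genes of the type 2 and regulatory cytokine list were measured, too few for a percentile. Of these the IL-1 antagonist gene Il1rn was 4.44-fold higher (17.0 and 75.6 FPKM, interval 3.85 to 5.14), while Ebi3 stood at 6.44 and 12.7 FPKM and Tgfb1 at 44.8 and 62.2. Neutrophil and monocyte markers, whose cells express many cytokine and chemokine genes, were higher in the same library, with median log2 ratios of 0.91 and 0.83.

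Chemokine genes showed larger differences. Of the 7 neutrophil-attracting CXC chemokine genes, 4 were at least 2-fold higher, and the list's median log2 ratio of 2.14 lay above all 10000 random lists. Cxcl5 stood at 2.73 FPKM in Adv-EV and 25.9 in Adv-IL-17B (9.48-fold higher, interval 6.14 to 14.9), and Cxcl2 at 5.30 and 42.7 FPKM (8.05-fold higher, interval 5.64 to 12.2). Cxcl3 was 7.53-fold higher (2.08 and 15.7 FPKM, interval 3.99 to 14.7) and Cxcl1 4.51-fold (3.62 and 16.3 FPKM, interval 2.73 to 7.88). These 4 genes lie near each other on chromosome 5 of mm10, between 90759360, the start of Cxcl5, and 90905938, the end of Cxcl2. Their neighbours Pf4 (34.2 and 44.4 FPKM), Ppbp (17.96 and 16.8 FPKM), both platelet products, and Cxcl15 (339 and 422 FPKM), a lung epithelial chemokine gene, differed by less than 2-fold. The 5 genes of the list of interferon-induced CXC chemokines and Cxcl13 had a median log2 ratio of 1.94, above all random lists, and 3 were past the size rule. Cxcl13, which attracts B cells, stood at 11.4 and 55.5 FPKM, Cxcl10, a ligand of CXCR3, at 25.7 and 108, and Cxcl11 at 0.90 and 3.74. Of 18 CC chemokine genes, 7 were higher and 2 lower by the rule (7 and 1 with a pseudocount of 1), with a median log2 ratio of 0.82 above all random lists. The monocyte attractant Ccl2, on chromosome 11 from 82035571 to 82037453, stood at 16.3 FPKM in Adv-EV and 107 in Adv-IL-17B (6.55-fold higher, interval 5.10 to 8.48). Ccl3 stood at 8.51 and 50.9 FPKM (5.98-fold higher, interval 4.18 to 8.75) and Ccl7 at 13.9 and 68.6 (4.93-fold higher, interval 3.76 to 6.65). Ccl20, which attracts cells bearing CCR6, stood at 0.65 and 3.67 FPKM on about 3 and 16 fragments (5.65-fold, interval 1.53 to 28.6). The lower genes were Ccl21a, a lymphatic chemokine with near-identical copies (105 and 49.9 FPKM), and Ccl25 (1.85 and 0.83 FPKM), both named after their values were seen.

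**Figure D2:**
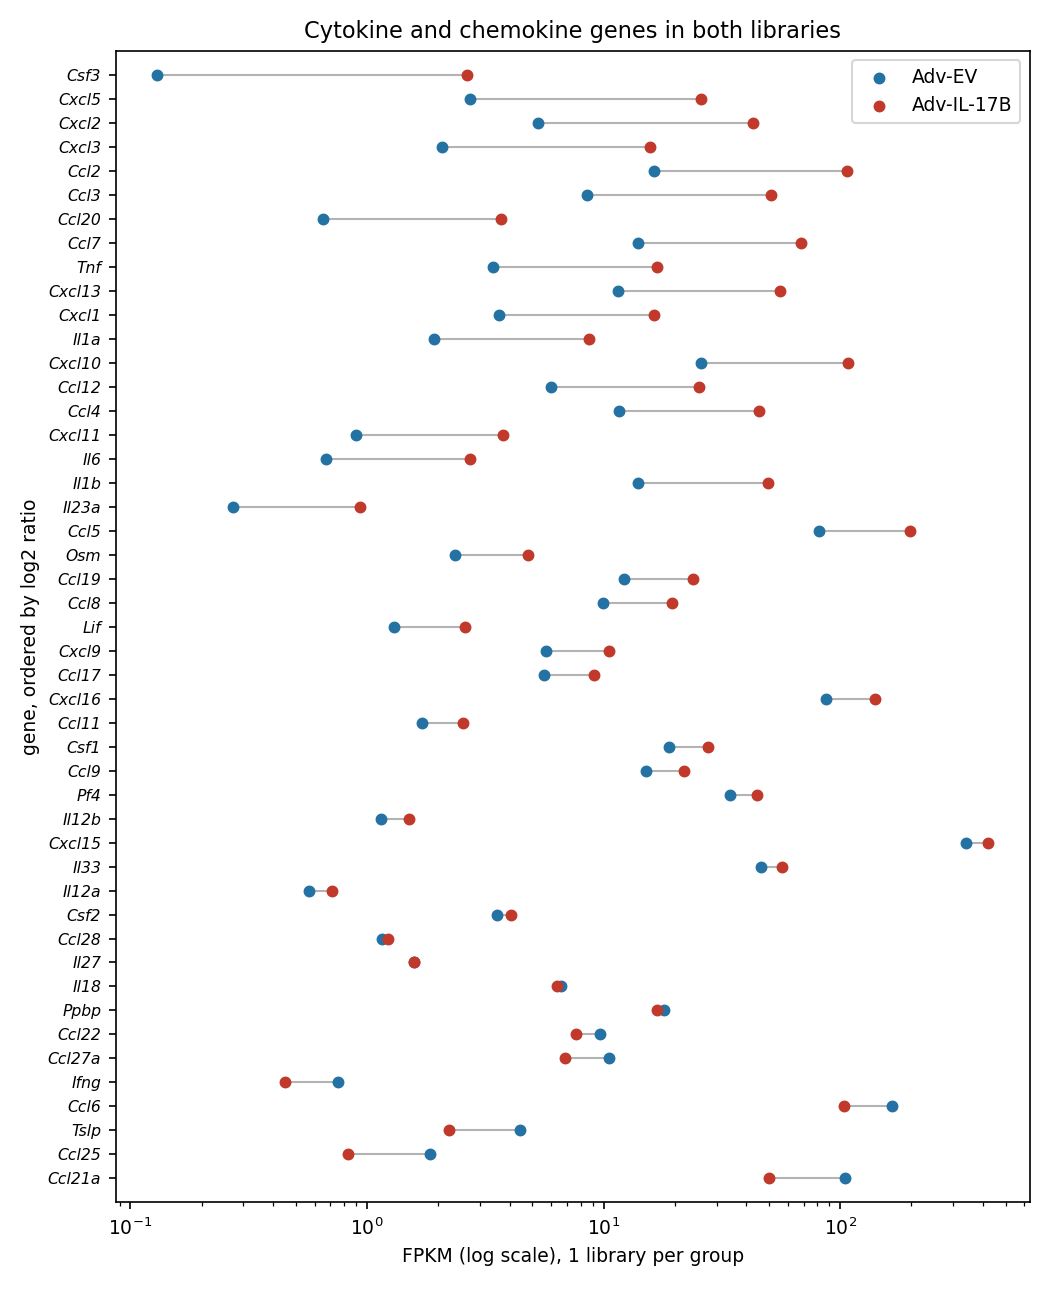
FPKM on a log scale (horizontal axis) of cytokine and chemokine genes in Adv-EV (blue) and Adv-IL-17B (red), 1 library each, with genes ordered by log2 ratio and a line joining the 2 values of each gene. Csf3, Cxcl5, Cxcl2 and Cxcl3 lead the list, and Ccl21a (105 and 49.9 FPKM) is at its foot.

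All 19 measured genes of the list that IL-17A induces in epithelium had a ratio above 0. Of these 7 were at least 2-fold higher in Adv-IL-17B (6 with a pseudocount of 1, without Mmp9) and 12 lay inside the 2-fold limits, with a median log2 ratio of 0.86 above all random lists. Besides Csf3, Cxcl5, Ccl20 and Cxcl1, the 7 included the antimicrobial lectin gene Reg3g, at 54.3 FPKM in Adv-EV and 224 in Adv-IL-17B (4.13-fold higher, interval 3.57 to 4.78). Mmp9, which is 1 of the 7, and S100a8 and S100a9 also stand in the neutrophil list, whose median log2 ratio was 0.91. Of 21 complement and acute phase genes, 6 were higher by the rule (5 with a pseudocount of 1, without Ptx3) and 0 lower, and the median log2 ratio of 0.55 lay above all random lists. C1qa, C1qb and C1qc of this list also stand in the monocyte and interstitial macrophage list, whose median log2 ratio was 0.83. Saa3, a serum amyloid A gene on chromosome 7 from 46711998 to 46715700, was among the most abundant, at 1454 and 6248 FPKM (4.30-fold higher, interval 4.16 to 4.44). The related Saa1 stood at 4.31 and 15.7 FPKM, and reads of serum amyloid genes may be split between copies. Orm1, which encodes the acute phase protein orosomucoid, stood at 20.3 and 84.3 FPKM and the pentraxin gene Ptx3 at 0.84 and 2.43. Of 19 NF-kappaB target and feedback genes, 4 were higher by the rule (3 with a pseudocount of 1, without Sele), with a median log2 ratio of 0.56 above all random lists. The 4 were the inhibitors Tnfaip3 (11 and 33.2 FPKM), Tnip1 (16.2 and 40.2 FPKM) and Nfkbie (8.09 and 17.8 FPKM) and the adhesion molecule gene Sele (0.37 and 1.47 FPKM, about 6 and 24 fragments). The list of mucus genes and genes of alternatively activated macrophages had 11 measured members, of which 4 were higher, with a median log2 ratio of 0.72 at percentile 99.96. Arg1, an arginine-degrading enzyme of such macrophages, stood at 5.35 and 27.0 FPKM (5.05-fold higher, interval 3.60 to 7.08) and Retnla at 1035 and 2157 FPKM (2.08-fold higher, interval 2.001 to 2.17). Itln1 (0.63 and 2.06 FPKM) and Clca1 (0.49 and 1.09 FPKM) rested on few fragments. With a pseudocount of 1 both were inside the 2-fold limits, at log2 ratios of 0.91 for Itln1 and 0.49 for Clca1, which left 2 of 11 genes higher. With the mean in place of the median this list no longer stood apart.

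Most interferon-related genes had a ratio above 0 and lay inside the 2-fold limits. All 29 type I interferon-stimulated genes had a ratio above 0, 8 of them past the size rule (6 with a pseudocount of 1), with a median log2 ratio of 0.64 above all random lists. Oasl1 stood at 10.9 FPKM in Adv-EV and 44.0 in Adv-IL-17B (4.03-fold higher, interval 3.31 to 4.92), and Rsad2, which encodes the antiviral enzyme viperin, at 17.2 and 64.4 (3.75-fold higher, interval 3.33 to 4.22). Mx1 stood at 7.13 and 19.4 FPKM and Ifit2 at 23.02 and 59.8. Of 19 interferon-gamma and guanylate-binding genes, 2 were past the rule, with a median log2 ratio of 0.55 above all random lists. They were Nos2, the inducible nitric oxide synthase gene (2.38 and 7.04 FPKM), and the signalling inhibitor gene Socs1 (11.9 and 32.5 FPKM). Gbp2 stood at 54.3 and 96.8 FPKM and Tgtp1 at 20.5 and 40.7, where the near-identical Tgtp2 makes the split of reads uncertain. The 12 genes of MHC class I presentation all had a ratio above 0 and 0 were past the rule. Their median log2 ratio of 0.38 lay at percentile 99.85, with H2-Q7, 1 of several near-identical class I genes, at 206 and 339 FPKM and the peptide transporter gene Tap1 at 75.5 and 121. The 10 MHC class II presentation genes had a median log2 ratio of -0.14 at percentile 3.99, within the random range, with H2-Eb1 at 493 and 382 FPKM and the class II regulator Ciita at 6.51 and 8.46. H2-DMb2 stood at 22.6 and 32.0 FPKM. The neutrophil and monocyte marker lists, with medians of 0.91 and 0.83, were higher in the same library.

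Markers of myeloid cells went in opposite directions. Of 16 neutrophil markers, 7 were at least 2-fold higher and 0 lower in Adv-IL-17B, with a median log2 ratio of 0.91 above all random lists. With genes listed at 0 set at their floor, 5 were higher and the median was 0.75, and 6 were higher with a pseudocount of 1. Il1r2, a decoy receptor for IL-1, stood at 3.20 FPKM in Adv-EV and 11.04 in Adv-IL-17B (3.45-fold higher, interval 2.18 to 5.61). Stfa1 and Stfa2, near-identical stefin genes, were listed at 0 in Adv-EV and stood at 1.38 and 1.27 FPKM in Adv-IL-17B, about 5 and 3 fragments. Camp (20.1 and 11.9 FPKM), Wfdc21 (14.9 and 10.2 FPKM) and Ngp (17.5 and 14.5 FPKM), named after their values were seen, had ratios below 0. The 18 monocyte and interstitial macrophage markers had a median log2 ratio of 0.83, above all random lists, with 7 higher by the rule. Ly6c2, a surface marker of inflammatory monocytes, stood at 102 and 285 FPKM (2.79-fold higher, interval 2.51 to 3.12), and Ms4a4c at 18.2 and 55.7. The Fc receptor gene Fcgr1 stood at 16.7 and 48.2 FPKM, and Itgam, which encodes the integrin CD11b, at 13.4 and 35.1. All 15 alveolar macrophage markers had a ratio below 0 and 5 were at least 2-fold lower, with a median log2 ratio of -0.70 below all random lists. Besides Krt79 and Cidec, the latter also in the adipocyte list, these included the scavenger receptor gene Marco, at 18.9 and 7.23 FPKM (2.61-fold lower, interval 1.99 to 3.42). Fabp1 was also among the 5, at 4.65 and 0.77 FPKM on about 14 and 2 fragments (6.04-fold, interval 1.61 to 63.5). The 13 dendritic cell markers had a median log2 ratio of -0.23 at percentile 3.70, within the random range. Among them Clec9a, a receptor of cross-presenting dendritic cells, stood at 11.6 and 7.45 FPKM, Zbtb46 at 6.10 and 4.31, Cd209a at 4.27 and 2.55 and the interferon-inducible Bst2 at 412 and 574. The 8 eosinophil, mast cell and basophil markers had a median log2 ratio of -0.38 at percentile 5.50, and the gene past the rule, Ear6, rested on about 7 fragments and 1.

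Lymphocyte and proliferation lists differed less. Of 18 NK and cytotoxic lymphocyte markers, 2 were past the rule (1 with a pseudocount of 1, without Klra4) and the median log2 ratio of 0.47 lay above all random lists. Ccl5 stood at 81.3 FPKM in Adv-EV and 198 in Adv-IL-17B (2.43-fold higher, interval 2.09 to 2.84) and the killer lectin-like receptor gene Klra4 at 1.71 and 3.73, while the granzyme gene Gzmb stood at 6.26 and 12.2. The 17 T cell markers included 0 past the rule and had a median log2 ratio of 0.31 at percentile 99.79. Cd5 stood at 2.87 and 4.85 FPKM, Cd8a at 3.42 and 5.30 and Cd28 at 1.61 and 1.07, and with the mean in place of the median the list no longer stood apart. The 14 B cell markers (median log2 ratio 0.04, percentile 72.2) and the 7 plasma cell markers (0.19, percentile 83.9, with a mean of -0.01) lay within the random range. Fcer2a stood at 9.62 and 17.6 FPKM and Cd79b at 16.6 and 26.4, and Jchain, which joins immunoglobulin polymers, at 2.64 and 1.53. Of 28 cell cycle genes, 26 had a ratio above 0 and 0 were past the rule, with a median log2 ratio of 0.36 above all random lists. Mki67, a marker of dividing cells, stood at 6.14 and 9.94 FPKM (1.62-fold higher, interval 1.41 to 1.86) and the replication gene Mcm5 at 12.9 and 20.6.

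Lists of structural lung cells lay below their random range by modest amounts. The 13 alveolar type 1 cell markers had a median log2 ratio of -0.36 at percentile 0.01, with 12 members below 0 and 0 past the rule. Igfbp2 stood at 216 FPKM in Adv-EV and 127 in Adv-IL-17B and Cav1, which encodes caveolin, at 379 and 268. The 14 alveolar type 2 cell markers (median log2 ratio -0.21) and the 11 surfactant and lipid secretion genes (-0.26) both lay at percentile 0.11. They are not separate results, as Sftpc, Sftpb, Slc34a2, Abca3, Lamp3, Napsa, Sftpa1 and Sftpd stand in both lists. Sftpc, which encodes surfactant protein C, stood at 20844 and 11922 FPKM (1.75-fold lower, interval 1.73 to 1.77), Sftpb at 1858 and 1461 and Slc34a2 at 341 and 262. The 18 endothelial markers had a median log2 ratio of -0.31 below all random lists, with Ednrb at 27.7 and 15.6 FPKM and Tek, the angiopoietin receptor gene, at 77.8 and 54.7. The 14 smooth muscle and pericyte markers (median log2 ratio -0.47) and the 19 fibroblast markers (-0.38) also lay below all random lists. In the former, 0 genes were past the rule, with Notch3 at 13.3 and 7.49 FPKM and the contractile protein gene Cnn1 at 11.6 and 7.49. In the latter 3 were lower, namely Inmt (901 and 405 FPKM, 2.22-fold, interval 2.12 to 2.34), Clec3b (106 and 52.0 FPKM) and Npnt (118 and 59.1 FPKM), the last inside the limit with a pseudocount of 1 or with the median of all genes set to 0. The 18 ciliated cell markers had a median log2 ratio of -0.25 at percentile 0.20, with Tppp3 at 380.1 and 269 FPKM and Sntn at 5.57 and 8.63. The 14 club and secretory airway cell markers went both ways. Reg3g and the airway defence gene Bpifa1 (24.7 and 51.4 FPKM) were higher by the rule, whereas the detoxifying enzyme genes Gsta3 (94.3 and 45.9 FPKM) and Cbr2 (3859.9 and 1882 FPKM) were lower. That list's median log2 ratio was -0.28 at percentile 0.04, and its mean of 0.04 had the opposite sign and did not stand apart. The 8 mesothelial markers (median log2 ratio -0.18, percentile 6.13) and the 20 extracellular matrix genes (0.16, percentile 91.9) lay within the random range. Upk1b stood at 13.9 and 6.61 FPKM, inside the limit with a pseudocount of 1, and Timp1, a metalloproteinase inhibitor gene, at 35.3 and 165 (4.68-fold higher, interval 3.96 to 5.54). Both of these lists stood apart under other settings. Basal airway cells had 3 measured markers, with Aqp3 at 1.27 and 2.59 FPKM, and cartilage had 2, Cytl1 at 9.41 and 5.07 and Col11a2 at 0.48 and 0.95.

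Red blood cell and clock genes were lower in the same library in which the cytokine and monocyte lists were higher. All 10 red blood cell and erythroid markers had a ratio below 0 and 7 were at least 2-fold lower (6 with a pseudocount of 1, without Slc4a1), with a median log2 ratio of -1.51 below all random lists. Hba-a1 stood at 3855 FPKM in Adv-EV and 1049.9 in Adv-IL-17B (3.67-fold lower, interval 3.55 to 3.80) and Hbb-bt at 558 and 166, with reads of these near-identical globin genes split in a way that is not known. Ahsp, a globin chaperone gene, stood at 4.24 and 0.38 FPKM and the red cell anion exchanger gene Slc4a1 at 1.01 and 0.08, about 25 fragments and 2. The 14 platelet and megakaryocyte markers had a median log2 ratio of -0.39 at percentile 0.28, with Gp5 at 3.16 and 0.89 FPKM and Clec1b, inside the limit with a pseudocount of 1, at 7.01 and 3.26. This list no longer stood apart with the mean or above 5 FPKM. Of 15 circadian clock genes, 13 had a ratio below 0, 4 were lower and 1 higher by the rule (4 and 0 with a pseudocount of 1, without Npas2), with a median log2 ratio of -0.68 below all random lists. Dbp, on chromosome 7 from 45705088 to 45710203, stood at 95.4 and 29.5 FPKM (3.23-fold lower, interval 2.83 to 3.69). The related Hlf stood at 6.31 and 2.22 FPKM and Tef at 81.3 and 36.3, and Npas2, whose rhythm runs opposite to that of Dbp, at 0.55 and 1.40. Clock (4.97 and 4.96 FPKM), named after its values were seen, counts among the 13 and changes sign when the median of all genes is set to 0. The hour at which each lung was taken is not given in the sources used here.

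Markers of muscle and fat were present at low to moderate levels. Whether they came from within the lung or from neighbouring tissue was not tested. The 18 cardiac muscle markers had a median log2 ratio of -0.36 at percentile 0.06, with Myl3 at 2.70 FPKM in Adv-EV and 0.41 in Adv-IL-17B and Tnnc1, inside the limit with a pseudocount of 1, at 8.21 and 3.96, while Mybpc3 stood at 0.73 and 1.54. This list did not stand apart with the mean. The 16 skeletal muscle markers had a median log2 ratio of -0.17 at percentile 1.32, with creatine kinase Ckm at 67.4 and 49.2 FPKM and Myh1 at 13.1 and 9.41. The 7 adipocyte markers had a median log2 ratio of -0.44 at percentile 5.36, within the random range, with Plin4 at 1.2 and 0.62 FPKM and Retn at 1.24 in Adv-EV and listed at 0 in Adv-IL-17B. This list stood apart with the mean or a pseudocount of 1.

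Lists that report on handling and scaling lay within the random range. The 18 immediate early and stress genes had a median log2 ratio of 0.11 (percentile 77.6), with 1 gene past the rule, Atf3, at 13.4 and 28.1 FPKM, and with Junb at 61.2 and 111. The 12 heat shock genes had a median of 0.02 (percentile 36.5), with Hspa1b at 9.10 and 6.14 FPKM. The 21 ribosomal protein genes all had a ratio above 0, with a median of 0.16 (percentile 75.8) and Rps2 at 884 and 1152 FPKM. Among the 12 common reference genes the median was 0.18 (percentile 87.9), with 9 ratios above 0 and 3 below. Actb stood at 1427 and 1731 FPKM and Gapdh at 565 and 795, 1.41-fold higher (interval 1.35 to 1.46). The Y-linked genes Ddx3y (12.6 and 11.4 FPKM), Eif2s3y (23.7 and 24.9), Kdm5d (3.38 and 3.44) and Uty (3.71 and 2.71) were present in both libraries, and Xist stood at 0.16 and 0.14. The 13 mitochondrially encoded genes of a further list were not analysed here.

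In all, 16 of the 43 lists with a percentile stood apart at the high end and 14 at the low end, against about 2.15 by chance for unrelated genes. Some lists share members, such as the surfactant and alveolar type 2 lists or the chemokine and IL-17A target lists, so they are not separate results. Genes of a list can vary together between any pair of mice, so these percentiles place the lists within these libraries and do not test the treatment.

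**Figure D3:**
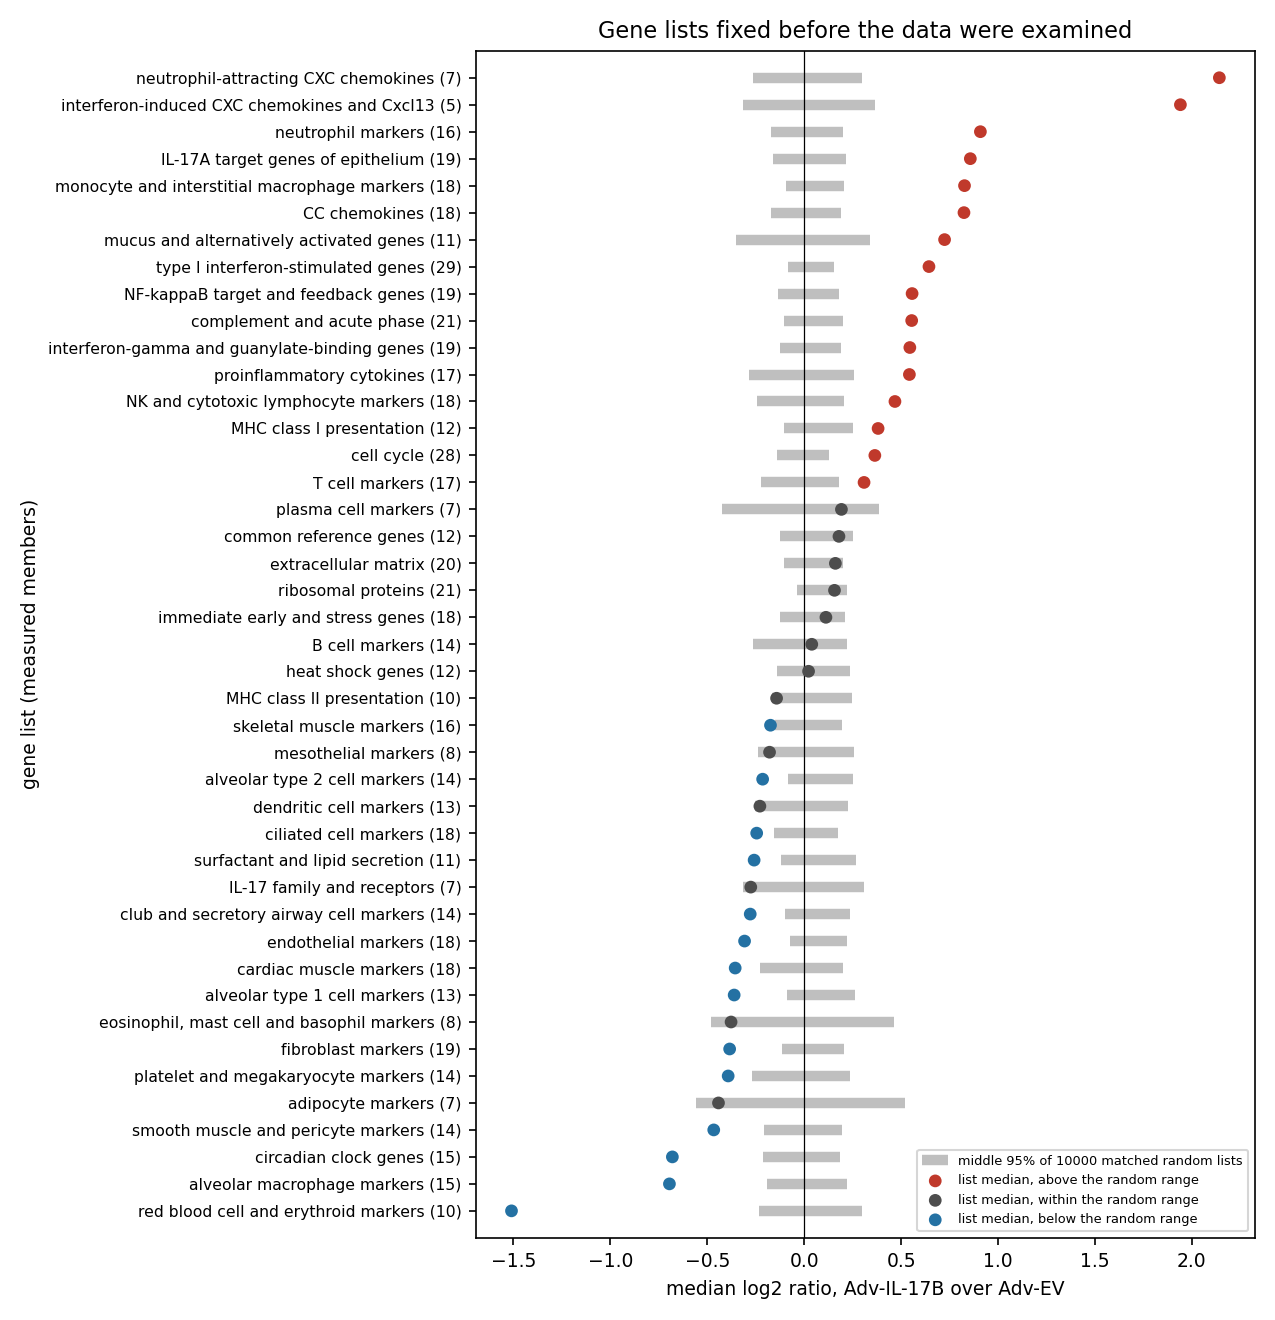
Median log2 ratio of Adv-IL-17B over Adv-EV (horizontal axis) for the 43 gene lists with at least 5 measured members (vertical axis, number of measured members in brackets), where each point is a list and each grey bar the middle 95% of 10000 matched random lists. Points run from -1.51 for red blood cell genes to 2.14 for neutrophil-attracting CXC chemokines, with 16 above their bar (red), 14 below (blue) and 13 within (dark grey).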

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

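The filter at 20 estimated fragments was chosen after the data were seen; the other alternatives were planned. The numbers of genes higher, lower and in all past the size rule were 352, 176 and 528 with a pseudocount of 1, 1147, 1012 and 2159 with no filter, and 224, 75 and 299 at a mean of 5 FPKM or more. They were 1422, 1235 and 2657 at 1.5-fold, 164, 107 and 271 at 4-fold, and 379, 200 and 579 with at least 20 estimated fragments. These counts follow from the rules themselves, since fewer or more genes can pass, and both rescalings and a pseudocount of 0.01 kept the counts within 1.5 times. Of 43 lists, 34 kept their place under every alternative that gave them a value, among them 14 of the 16 high and 11 of the 14 low lists. Lists without a value under an alternative, named below, were judged on the others. With the mean over a list, the club cell list turned from -0.28 to 0.0441 and no longer stood apart. With the mean, the mucus (0.77), T cell (0.20), platelet (-0.39) and cardiac (-0.28) lists no longer stood apart. The IL-17 family (1.12), extracellular matrix (0.28), mesothelial (-0.27) and adipocyte (-1.23) lists then did. A pseudocount of 1 set the adipocyte list apart (-0.38), and no filter the mesothelial list (-0.36). At 5 FPKM or more the matrix (0.22) and mesothelial (-0.44) lists stood apart and the platelet list (-0.19) did not. The cause of these changes was not tested. The interferon-induced CXC chemokine and eosinophil lists had too few members for a value at 5 FPKM or at 20 fragments, and the plasma cell and adipocyte lists at 5 FPKM. Of 224 named genes, which were run under the pseudocounts and the rescalings only, 202 kept their side of the size rule. Direction was not put to a test, because a pseudocount cannot change the sign of a ratio and the rescalings moved all ratios only slightly. Rescaling to the same total moved the median log2 ratio of all genes to -0.02, and depth limits genes of few fragments: Il6, Csf3, Ccl20 and Il17rb rested on about 4, 1, 3 and 7 fragments in Adv-EV.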

Other observations

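The gene families in the next 2 paragraphs, and the tests on red blood cell, neutrophil and alveolar macrophage genes, were chosen after the result was seen, as were the genes named here and not in the report, while the tests on clock genes were written before their values were looked at.

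Several receptors that sense microbes and damaged cells were higher in the Adv-IL-17B library. Of 11 measured Toll-like receptor genes, 4 were at least 2-fold higher (2 with a pseudocount of 1) and 0 at least 2-fold lower, with Tlr2 at 19.2 FPKM in Adv-EV and 50.8 in Adv-IL-17B. Tlr5, a receptor for flagellin (3.29 and 2 FPKM), and Tlr12 (2.98 and 1.80 FPKM) had ratios below 0. C-type lectin genes with a Clec symbol went both ways, as 7 of 21 were higher by the rule, 3 were lower (6 and 1 with a pseudocount of 1) and 11 had a ratio below 0. Clec4d stood at 12.8 and 72.0 FPKM and its genomic neighbour Clec4e at 5.69 and 36.6, while Clec12b (1.66 and 0.47 FPKM), Clec1b (7.01 and 3.26 FPKM) and Clec3b (106 and 52.0 FPKM) were lower. Fpr2, a receptor for formyl peptides and for serum amyloid A, stood at 5.61 and 26.1 FPKM, and Nlrp3, an inflammasome sensor gene, at 2.53 and 10.1. Neutrophil and monocyte markers were higher in the same library, with median log2 ratios of 0.91 and 0.83.

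Most genes of enzymes that handle foreign compounds had a ratio below 0, and most lay inside the 2-fold limits. Of 64 measured genes of the cytochrome P450 families 1 to 4, flavin monooxygenases, glutathione transferases, carboxylesterases, sulfotransferases, Aldh1a and carbonyl reductases, 48 had a ratio below 0. By the 2-fold rule 11 were lower and 2 higher (8 and 1 with a pseudocount of 1), with a median log2 ratio of -0.53. Marker lists of structural cells were lower as well, with medians of -0.38 for fibroblasts, -0.36 for alveolar type 1 cells, -0.31 for endothelium and -0.28 for club cells, and Cyp2f2, Cbr2, Gsta3, Aldh1a7 and Cyp2b10 are themselves members of the club cell list. Cyp1a1, a target of the aryl hydrocarbon receptor, stood at 17.5 FPKM in Adv-EV and 6.16 in Adv-IL-17B, Cyp2a5 at 14.0 and 4.94 and Gsto2 at 2.13 and 0.29. Fmo2, the main lung flavin monooxygenase, stood at 158 and 73.6 FPKM and Aldh1a1 at 486 and 266. The genes higher by the rule were Cyp4f18, a leukotriene-metabolising enzyme of neutrophils (48.2 and 133 FPKM), and Cyp1b1 (1.66 and 4.01 FPKM).

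Clock genes were lower in Adv-IL-17B, with Dbp, Tef, Hlf and Nr1d1 at least 2-fold lower and Npas2 higher, the last not with a pseudocount of 1. Arntl, the other clock gene with a ratio above 0, stood at 1.57 FPKM in Adv-EV and 2.92 in Adv-IL-17B, inside the 2-fold limits. If the lungs differed in clock phase, other output genes should have been lower too. Usp2 and Wee1 together had a log2 ratio of -0.38 (interval -0.60 to -0.15 for counting error only, 375 and 289 estimated fragments), which with 1 library per group does not settle it, so a different clock phase, from the hour of collection or from the treatment, remains a candidate explanation, and the design cannot separate these. A weaker glucocorticoid response would lower its target genes. The median log2 ratio of 8 such genes was -0.18 (bootstrap interval -0.66 to 0.15) at percentile 5.93, with Klf9 at 32.5 and 14.4 FPKM and Fkbp5 at 10.9 and 10.02, and because members went both ways this stays open.

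Red blood cell genes lay furthest below their random lists, at a median log2 ratio of -1.51. Less whole blood in the Adv-IL-17B lung would lower platelet genes by about as much. Their median log2 ratio was -0.39 (bootstrap interval -0.72 to -0.10), or -0.49 (bootstrap interval -0.76 to -0.15) over the 11 genes other than Vwf, Pf4 and Itgb3, which other cells also express. Both lie above the red cell value. With 1 library per group and intervals that cover only the spread between genes, this does not decide on less blood. Platelets may also be held in inflamed lung. A difference in young red cells or reticulocytes between the mice was not tested and could contribute.

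Monocyte and neutrophil genes were higher while alveolar macrophage genes were lower. Red cell genes held 1.79% of the summed FPKM in Adv-EV and 0.560% in Adv-IL-17B, and losing that share could lift other genes by 0.0179 on the log2 scale, against a median log2 ratio of 0.83 for monocyte markers. More neutrophils with unchanged expression per cell would give all their markers 1 ratio only if no other cells expressed those markers. Of 16 markers, 8 had counting intervals that missed the pooled log2 ratio of 0.88. Mmp9, S100a8 and S100a9 are also in the list of genes that IL-17A induces in epithelium, so these misses cannot decide on neutrophil number. For fewer alveolar macrophages with unchanged expression per cell, 8 of 15 markers missed the pooled log2 ratio of -0.49. Car4 is also in the endothelial list, and Cidec and Fabp4 are also in the adipocyte list. These intervals cover counting error only and leave out differences between mice and library preparations, so cell numbers, expression per cell and such differences may each contribute and were not separated.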
